A study of Drosophila melanogaster with 4 samples.

How the data were processed

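The study mapped Chromator (Chro, also called Chriz), a chromodomain protein known from the interbands of polytene chromosomes, by chromatin immunoprecipitation and sequencing (ChIP-seq) in Drosophila melanogaster. Wild-type Oregon-R embryos aged 14 to 16 hours were used. There were 4 samples, namely 2 ChIP samples made with the antibody the labels call WR and 2 input samples. Per the labels' protocols, embryos were fixed in 1.8% formaldehyde and the chromatin was precleared before the antibody was added. Each input sample is labelled as having served 1 of the ChIP lists. The labels number the samples 1 and 2 in each group but do not say whether the replicates came from separate embryo collections, so the spread between them may be partly technical.

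The analysis used 3 lists of enriched regions, namely 1 per ChIP sample and 1 for the set of both replicates, called the combined list here. Per the submitters' processing notes, Bowtie 0.12.7 was used. Per the file headers, the coordinates are those of FlyBase release 5 of the genome. The region caller, its threshold and the way the replicates were combined are not given in the sources used here. Read totals are not part of the lists, so the sequencing depth behind each list is unknown and no value has an error from read counting. The shortest region is 1301 bp in each replicate list and 1001 bp in the combined list, so the authors' lists were not made with 1 common minimum width.

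Each deposited region carries 1 score, which is on a log2 scale. The scale is not named by the authors and was read from the values. Raised as a power of 2, 3985 of 3987 scores of replicate 1, 3841 of 3841 of replicate 2 and 5758 of 5762 of the combined list were ratios of 2 whole numbers times 1 constant per list. A relative tolerance of 1e-09 and denominators up to 3000 were allowed. Of 3000 random numbers treated the same way, 0.1% passed. What was counted in those whole numbers is not stated. Scores are the authors' own values and were compared only within a list, except for the correlation of paired regions and the SD of their score difference between the replicates.

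Regions were called overlapping when they shared at least 1 bp. Shares of regions have Wilson 95% intervals, which cover counting error only. Replicate overlap was set against 1000 circular shifts of the other list within each sequence, which keep widths and spacing. Scores of regions found by both replicates or by 1 were compared by a two-sided permutation test with 100000 resamples of the labels. The X was compared with the autosomal arms 2L, 2R, 3L and 3R by the same kind of test over full 200 kb bins, assigning a region to a bin by its midpoint. Neighbouring bins and neighbouring regions are not independent, so the p-values from shuffling them may be too small. They also describe the 2 ChIP samples and not a wider population of embryos. Regions found in both replicates means regions of replicate 1 that replicate 2 overlapped. Rates per gene used the number of protein-coding genes per chromosome in the RefSeq table of Release 6, with exact conditional binomial tests. These treat regions as independent, and since regions were clustered their intervals are too narrow. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap, binning and ratio steps were tested on simulated lists. With a partner made for 61.1% of the 3987 replicate 1 regions, 61.4% were found, and a score difference of 0.15 added to the X was found as 0.16.

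The reference table has the coordinates of Release 6 and not those of release 5, and coordinates were not carried between releases. The 4 tests planned on promoters, divergent promoters, preset gene lists and promoter motifs were therefore not run, and regions are named by position, with no gene or exon annotation. The rule for named regions was fixed before the data were examined. It takes the 10 highest-scoring combined-list regions that both replicates overlap and the 3 widest combined-list regions. The overlap, score, combined-list and X density comparisons were also fixed then. The comparisons of scores between arms, of rates per gene and of the 100 highest scores, the test of scaffold regions, the widths of combined-list regions, the spacing and the windows along the arms were chosen after seeing the data. Alternatives were other overlap minimums, the 50% of each list with the highest scores, merging of neighbouring regions, other bins, the combined list, combined-list regions at least as wide as the shortest replicate region, and each replicate left out.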

Results

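Chromator-enriched regions were listed for 2 ChIP-seq replicates of Oregon-R embryos aged 14 to 16 hours. Replicate 1 had 3987 regions covering 9.19 Mb and replicate 2 had 3841 regions covering 8.59 Mb. These make up 5.44% and 5.09% of the 169 Mb of sequence declared in the headers. The regions were of similar size in both, with a median width of 2155 bp in replicate 1 and 2119 bp in replicate 2. The median score was 0.87 in replicate 1 and 0.88 in replicate 2 on the log2 scale, a ratio of 1.83 and 1.84. The combined list held 5762 regions covering 12.5 Mb, with a median width of 2125 bp and a median score of 0.65.

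The first comparison asked how far the 2 replicates marked the same places. Of the replicate 1 regions, 3490 (87.5%, 95% interval 86.5 to 88.5) were overlapped by a replicate 2 region. Of the replicate 2 regions, 3513 (91.5%, 90.5 to 92.3) were overlapped by a replicate 1 region. Circularly shifted lists overlapped 13.3% ± 0.64 (SD, 1000 shifts) and 13.8% ± 0.66 of regions, and no shift passed 18.4%, so the one-sided permutation p was 0.001 both ways, the smallest that 1000 shifts can give. The replicates shared 7.71 Mb, which is 76.7% of the 10.1 Mb in regions of either. In 3389 cases 1 region of each list overlapped only the other. The midpoints of these pairs lay a median of 55 bp apart, and 90% were within 224 bp. No pair had the same start and end or the same score, so the lists are not copies.

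Region scores rose and fell together in the replicates. Across the 3389 pairs, Pearson's r was 0.80 and Spearman's rho 0.78. Region counts in 593 bins of 200 kb along the 5 large arms had r = 0.96 and rho = 0.96. Each of these 4 correlations had a permutation p of 1e-05, also after Benjamini-Hochberg adjustment, which is the smallest that 100000 resamples can give. They are correlations across regions or bins, which are not independent replicates. Regions found by only 1 replicate had lower scores. In replicate 1 the 497 unshared regions had a median score of 0.62 (quartiles 0.54 to 0.70) against 0.92 (0.71 to 1.15) for shared regions, a difference of 0.31 (permutation p = 1e-05, two-sided). In replicate 2 the 328 unshared regions had a median of 0.70 (0.60 to 0.78) against 0.91 (0.72 to 1.14), a difference of 0.21 (permutation p = 1e-05). Unshared regions were also narrower, with a median of 1701 bp against 2195 bp in replicate 1 and 1612 bp against 2145 bp in replicate 2.

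**Figure D1:**
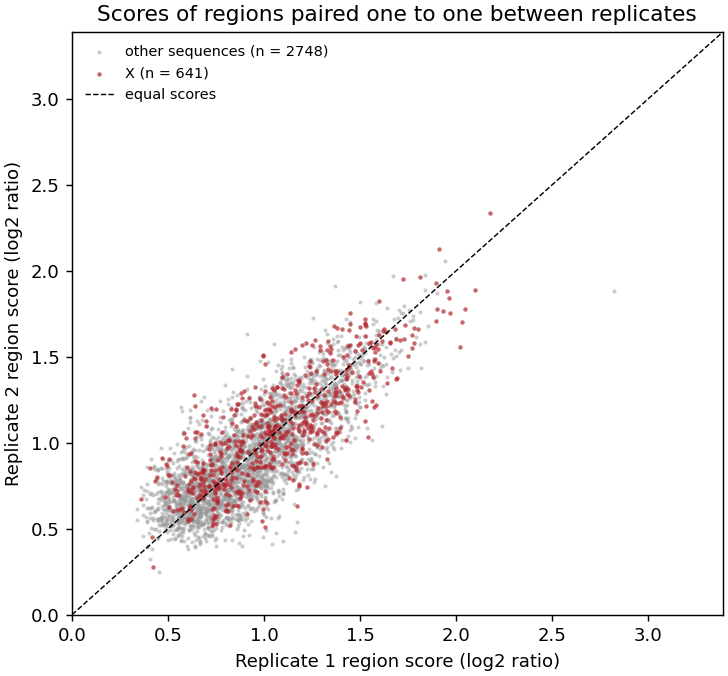
Score of each of 3389 one-to-one paired regions in replicate 1 (x axis) and replicate 2 (y axis), both as log2 ratios, with 641 regions on the X in red, 2748 on other sequences in grey and a dashed line at equal scores. The points follow the dashed line with r = 0.80, and X regions are frequent at the upper end.

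The second comparison placed the regions on the chromosomes. Chromator regions found in both replicates lay almost entirely on the 5 large arms, with 3403 of 3490 there. Arm 2R was the most densely marked large arm, with 690 regions or 32.6 per Mb (exact Poisson interval 30.2 to 35.2). The Poisson intervals treat regions as independent, and since regions were clustered they are too narrow. The X had 659 regions or 29.4 per Mb (27.2 to 31.7), 3R had 815 or 29.2 per Mb (27.2 to 31.3), 3L had 640 or 26.1 per Mb (24.1 to 28.2) and 2L had 599 or 26.0 per Mb (24.0 to 28.2). The small chromosome 4, known for its heterochromatin-like chromatin, had 41 regions or 30.3 per Mb (21.8 to 41.1). Of 86 windows of its length on the large arms, 37 had as many regions. The 6 scaffolds of heterochromatic sequence assigned to arms (Het) had 33 regions on 9.28 Mb, or 3.56 per Mb, and the scaffold of unplaced sequence (U) had 13 on 10.0 Mb, or 1.29 per Mb. No region was listed on the second unplaced scaffold, Uextra.

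The regions were unevenly spread along the arms. With a median of 28 regions per 1 Mb window in both replicates, the fullest window was at 10000001 to 11000000 of 2L with 55 regions. Next came 5000001 to 6000000 of 3R with 54 and 15000001 to 16000000 of the X with 50. The emptiest were 14000001 to 15000000 of 2L and 23000001 to 24000000 of 3L with 7 each, and 17000001 to 18000000 of 2L with 9. The longest stretches of the large arms without a region in any of the 3 lists were 325 kb on 2L (14363031 to 14688359), 297 kb on 2L (3890259 to 4186775) and 291 kb on the X (21505013 to 21796465).

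**Figure D2:**
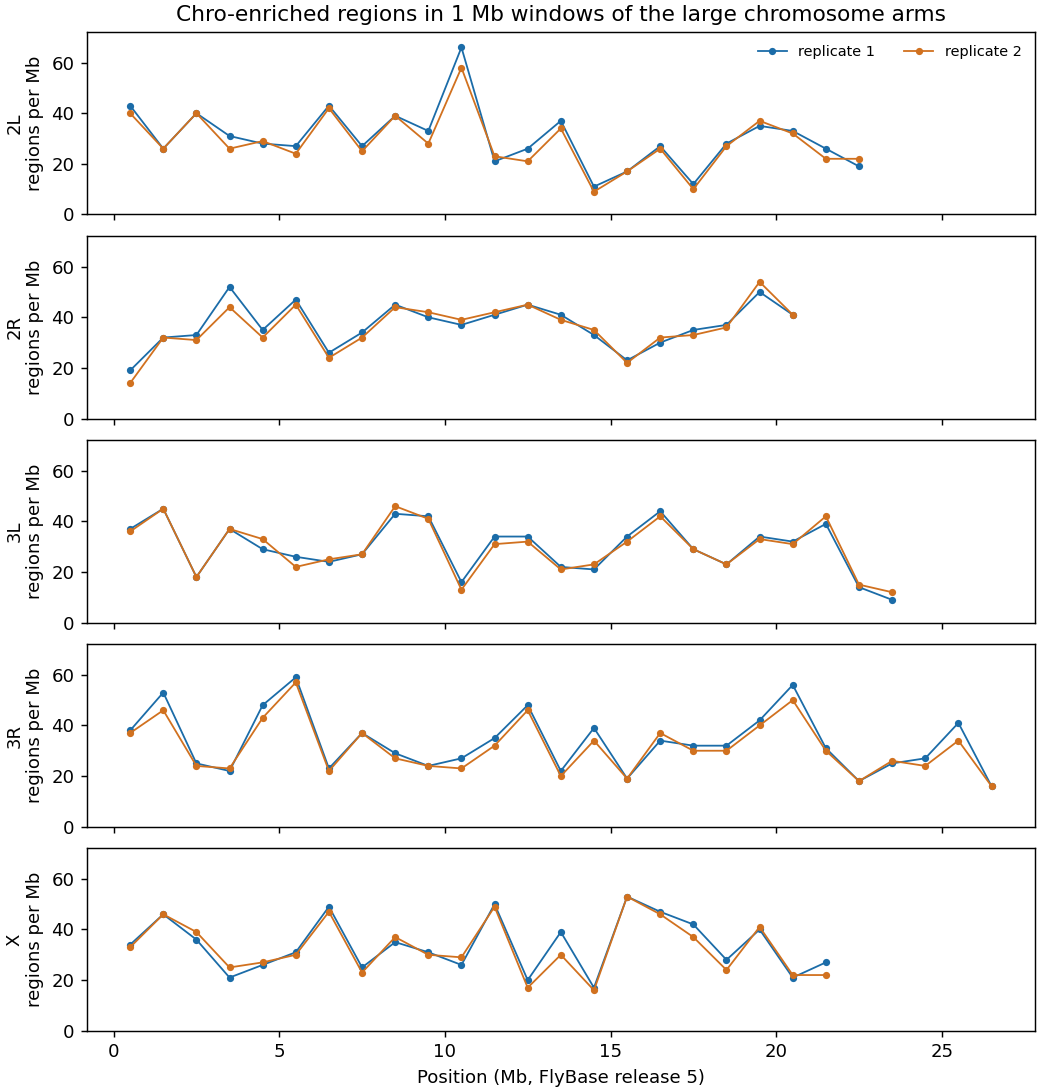
Number of enriched regions in each full 1 Mb window (y axis) along the 5 large arms (x axis, position in Mb on FlyBase release 5) for replicate 1 in blue and replicate 2 in orange. Both replicates peak in the window from 10 to 11 Mb of 2L, with 66 and 58 regions, and fall to 11 and 9 regions between 14 and 15 Mb of 2L.

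The X did not carry a detectably different number of regions per length than the autosomes, but its regions scored higher. In 112 bins of 200 kb the X had 29.3 ± 20.7 regions per Mb (SD over bins) against 28.5 ± 19.5 in 481 autosomal bins, a difference of 0.83 that was within the spread between bins (permutation p = 0.69, two-sided). Among the 50% of regions with the highest scores in each replicate list the difference was 6.26 regions per Mb (permutation p = 1e-05), which restates the higher X scores, since the regions were selected on score. The mean score per bin was 1.08 ± 0.18 on the X (103 bins with a region) and 0.94 ± 0.17 on the autosomal arms (448 bins). The difference was 0.14 on the log2 scale, or 1.10-fold (permutation p = 1e-05, 2e-05 after adjustment over the 4 arm comparisons). The replicate 2 scores of regions that replicate 1 overlapped gave 0.16, the combined list 0.09, and the 50% of regions with the highest scores 0.06, or 1.04-fold. In each replicate list, the median score of the X (1.00 in replicate 1 and 1.03 in replicate 2) was above that of each of the 4 autosomal arms, which ranged from 0.82 to 0.87 in replicate 1 and from 0.83 to 0.86 in replicate 2. Chromosome 4 had medians of 0.86 and 0.87. Among the 100 highest-scoring combined-list regions found in both replicates, 45 were on the X and 52 on the autosomal arms. That is 6.94% of the X regions and 1.92% of the autosomal ones (Fisher's exact test across regions, two-sided p = 7e-10). This count also restates the higher X scores, and the test treats clustered regions as independent.

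**Figure D3:**
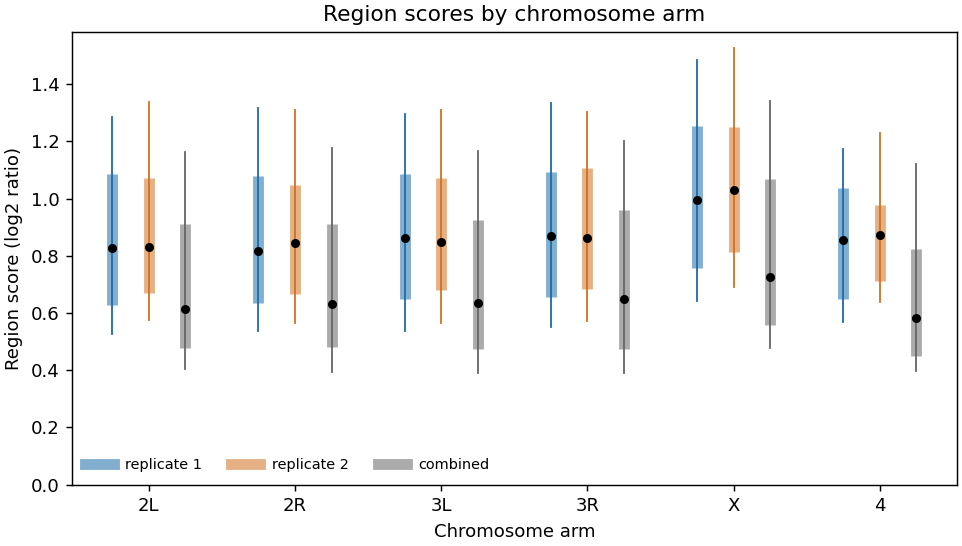
Region scores (y axis, log2 ratio) by chromosome arm (x axis) in replicate 1 (blue), replicate 2 (orange) and the combined list (grey), with the median as a black dot, the quartile range as a thick bar and the 10th to 90th percentile range as a thin line. In all 3 lists the median on the X (1.00, 1.03 and 0.73) is the highest of the 6 arms shown.

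Set against gene number, both chromosome 4 and the X had more regions than the other arms. Chromosome 4 had 51.3 regions found in both replicates per 100 protein-coding genes, against 24.6 on the 5 large arms, a ratio of 2.08 (exact 95% interval 1.49 to 2.83, exact two-sided p = 2.3e-05, adjusted 3e-05). The X had 30.0 per 100 genes against 23.6 on the autosomal arms, a ratio of 1.27 (1.17 to 1.39, exact p = 5.8e-08, adjusted 2.3e-07). Genes of these chromosomes were longer, with a mean of 13.1 kb on chromosome 4, 8.20 kb on the X and 6.62 kb on the autosomal arms. Per Mb of summed gene length the ratios were 1.09 for chromosome 4 (0.78 to 1.49, exact p = 0.56) and 1.03 for the X (0.94 to 1.12, exact p = 0.54). Per Mb of sequence, chromosome 4 had 30.3 regions against 28.6 on the 5 large arms. The X had 29.4 against 28.4 on the autosomal arms. For regions found in both replicates, the higher ratios per gene thus mostly reflect fewer genes per length on these chromosomes. In the combined list, chromosome 4 was denser also per Mb of sequence, with 58.4 regions against 45.6 on the 5 large arms.

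Of the 10 combined-list regions with the highest scores among those both replicates overlapped, 8 were on the X, 1 on 3R and 1 on U. Among all combined-list regions these 10 ranked from 28 to 65. The highest was at 9709970 to 9712692 of U, with a score of 2.50 in the combined list, 2.82 in replicate 1 (rank 2) and 1.88 in replicate 2 (rank 16). The next was at 10660576 to 10663716 of the X, with a score of 2.07 (rank 5 of 3987 in replicate 1 and 3 of 3841 in replicate 2). A second strong region lay near it, at 10637484 to 10640476, with a score of 1.87 (ranks 15 and 4). The other 6 on the X began at 1405816, 7953754, 11587852, 15032376, 19576458 and 19758624, with scores from 1.85 to 1.91. The region on 3R was at 27044180 to 27048100, close to the end of that arm, with a score of 1.87 and rank 17 in both replicate lists. The 3 widest combined-list regions were 10041 bp at 9049680 to 9059720 of the X, 8977 bp at 9389132 to 9398108 of 2R and 8299 bp at 19494822 to 19503120 of the X. Their scores of 0.88, 0.97 and 0.78 were well below those of the strongest regions, and each spanned 1 to 3 regions of each replicate.

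The third comparison asked which regions the combined list added. It overlapped 98.9% of the replicate 1 regions and 98.4% of the replicate 2 regions, and it comes from the same samples, so this is no independent evidence. Of its 5762 regions, 3445 (59.8%, 58.5 to 61.0) were overlapped by both replicate lists, 699 (12.1%) by 1 and 1618 (28.1%, 26.9 to 29.3) by neither. The lists differ in their shortest region, 1301 bp in each replicate list and 1001 bp in the combined list, and 1008 of the 1618 regions overlapped by neither were narrower than 1301 bp. Their median width of 1196 bp, against 2361 bp for regions overlapped by both, is thus partly set by how the lists were made. Their median score was 0.49, against 0.87 for regions overlapped by both. Among combined-list regions of at least 1301 bp, 610 of 4690 were overlapped by neither, with a median width of 1542 bp and a median score of 0.43, and 73.5% were overlapped by both. Of the 50% of combined-list regions with the highest scores, 91.6% were overlapped by both.

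The added regions lay more often on heterochromatic and unplaced sequence. On the Het and U scaffolds together, 168 of 256 combined-list regions (65.6%, 59.6 to 71.2) were overlapped by neither replicate list, against 26.3% elsewhere (Fisher's exact test across regions, odds ratio 5.34, two-sided p = 2.1e-37). Among regions of at least 1301 bp the odds ratio was 3.89 (Fisher's exact p = 7.7e-11), and among the 50% with the highest scores it was 60.4 (p = 9.9e-101), so its size depends on which regions are counted. The share was 72.5% on U, 58.4% on the Het scaffolds, 39.2% on chromosome 4 and 26.1% on the large arms. Scores of these added regions were highest on U, with a median of 1.21 (quartiles 0.76 to 2.18), and lowest on chromosome 4 with 0.46. Of the 50 highest scores in the combined list, 45 belonged to regions that neither replicate list had, and 36 of the 50 were on Het or U scaffolds. These 50 had a median width of 1009 bp. Of the 45, 39 were narrower than any region of a replicate list and 6 were not.

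**Figure D4:**
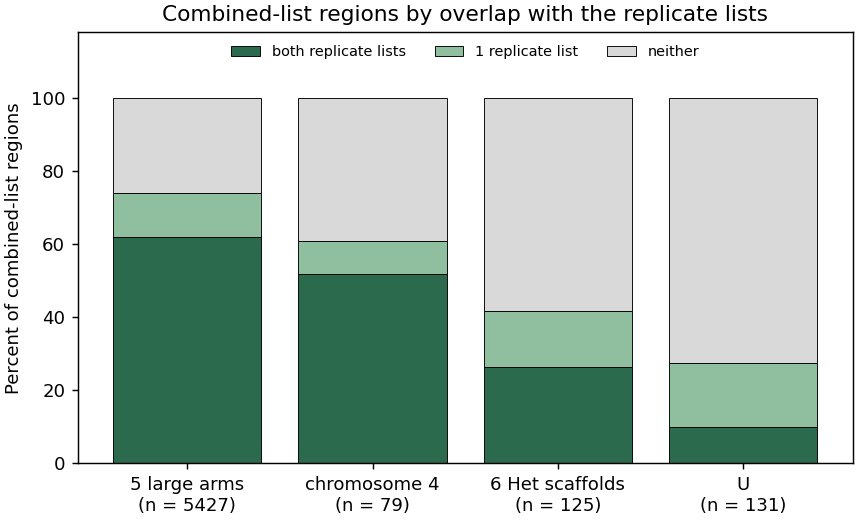
Percent of combined-list regions (y axis) overlapped by both replicate lists (dark green), 1 list (light green) or neither (grey) on the 5 large arms, chromosome 4, the 6 Het scaffolds and U (x axis, with the number of regions). The share overlapped by both is 61.9% on the large arms, 51.9% on chromosome 4, 26.4% on Het and 9.92% on U.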

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

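The tests of tied scores, of the share on scaffolds, of widths and of distances against random moves within a short distance were chosen after the result was seen, the last because circular shifts, chosen before, do not keep the clustering of regions along the arms. Heterochromatic and unplaced scaffolds, which the comparison of the X with the autosomal arms leaves out, carried listed regions in every list. Replicate 1 had 46 regions on the Het scaffolds and 31 on U, replicate 2 had 45 and 21, and the combined list had 125 and 131. Per length these counts were low. Het and U together had 3.98 regions per Mb in replicate 1, 3.41 in replicate 2 and 13.2 in the combined list. The large arms had 32.5, 31.3 and 45.6. The small XHet scaffold differed from the pooled value, with 34.3, 19.6 and 63.7 per Mb, from few regions (7 in replicate 1 and 4 in replicate 2). The counts were flagged only because the X comparison leaves these scaffolds out. No list of the input samples was used here, so no background count is known.

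The pattern weighed is the group of 1618 combined-list regions that neither replicate list overlapped. Scaffold sequence could not be the whole cause, since the combined list has only 256 regions on Het and U scaffolds. The 10.4% of the 1618 regions found there was thus bound to be small and is no test of its own. The lower minimum width of the combined list as the whole cause is argued against. Of the 1618 regions, 62.3% (59.9 to 64.6) were narrower than the shortest replicate region, which leaves that share open to it. Few counts behind the score may explain part of the group. Of its scores, 53.9% were exactly tied with another region's, against 10.2% of regions overlapped by both replicate lists. As ratios in lowest terms, the median numerator and denominator were 109 and 142.5, against 355 and 391. The group was also narrower, and its scores lay closer together (quartiles 0.42 to 0.56 against 0.67 to 1.08), which can raise ties too. The tied share is thus no support separate from the widths of these regions. Those on the large arms lay a median of 12659 bp from the nearest region overlapped by both lists, nearer than in any of 1000 circular shifts (lowest 17421 bp) or of 1000 random moves within 50 kb (lowest 16000 bp, and 14932 bp within 20 kb) but further than such regions lay from each other (3979 bp), so weak enrichment beside strong regions and the clustering of all regions cannot be told apart. Repeated sequence could not be examined without the genome of this release, and no biological explanation was tested.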

How the results depend on the processing

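The alternatives for the X scores, the rates per gene, the 100 highest scores, the spacing and the scaffold odds ratio, and the limit on width, were chosen after seeing the data. Of 41 alternative values for 12 results, 37 kept their direction and their side of the threshold or stayed within the main interval, and none turned its direction. Those for the rates per gene all kept gene number as the base. Per Mb of summed gene length, which the tally leaves out, the ratios were 1.09 (0.78 to 1.49) for chromosome 4 and 1.03 (0.94 to 1.12) for the X. The share of combined-list regions overlapped by both replicate lists went from 59.8% to 58.0% when 50% of the combined region had to be covered, and to 91.6% in the 50% of the combined list with the highest scores, for which the cause was not tested. It went to 73.5% among regions at least as wide as the shortest replicate region, a limit that by construction removes narrow regions the replicate lists do not hold. The scaffold odds ratio of 5.34 was 60.4 in the 50% with the highest scores and 3.89 with the limit on width. The difference in region density between the X and the autosomal arms passed the threshold only in the 50% of each list with the highest scores, at 6.26 regions per Mb, where the higher X scores by construction place more X regions in that part. The X score difference of 0.14 fell to 0.06 (permutation p = 0.0005) in the 50% of each list with the highest scores and to 0.09 in the combined list. Leaving out each replicate in turn gave chromosome 4 ratios per gene of 2.06 and 2.18, and X density differences of 0.89 and 1.15 regions per Mb. The X score difference was 0.14 in the whole replicate 1 list. It was 0.16 with the replicate 2 scores of regions that replicate 1 overlapped, which still depends on replicate 1. No paired analysis was possible because the input samples have no list of their own here and no test compared them with the ChIP samples. The alternatives for promoters, divergent promoters, gene lists and motifs were not run, since those results need an annotation of release 5. Depth limits the lists in a way that cannot be measured from them, as no read totals are given, and 2 ChIP samples allow no test between samples.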

Other observations

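In this part, the spacing, the values next to the centromere and the threshold test, which replaced another comparison of percentiles that could not decide, were chosen after seeing the data, and the tests of clustering, noise, merged domains and gene length before their results were seen. Chromator regions found in both replicates sat in clusters. Of 3398 gaps between neighbours on the large arms, 34.7% were within 5 kb, against 14.3% ± 0.50 (SD) and at most 15.9% in 200 random placements of the same regions. The median gap was 9844 bp against 22443 bp. In the 1 Mb of sequence nearest the centromere, 3L had 2 regions found in both replicates against 27.1 per Mb in the rest of the arm, X had 13 against 30.2, 2R had 14 against 33.6 and 2L had 17 against 26.4. Arm 3R differed in direction, with 33 against 29.1, and no test was made of these values.

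The higher scores on the X were weighed first. A higher cutoff on the score there as the whole cause is argued against by regions above the median score of their list, a common limit. Among them the X still scored higher by 0.082 (95% bootstrap interval over bins 0.04 to 0.12) in replicate 1 and 0.073 (0.03 to 0.10) in replicate 2. The 10th percentile was also higher on the X, by 0.10 and 0.12, and a contribution is not excluded. The caller's threshold is unknown, so a higher threshold on a measure other than the score stays open. Closer clustering is argued against too, since regions over 5 kb from their neighbours still differed by 0.16 (0.10 to 0.21) in replicate 1 and 0.15 (0.10 to 0.19) in replicate 2. For noise, the SD of the score difference between paired replicates on the X was 1.05 times that of the autosomes (0.99 to 1.12). The upper bound lay below the limit set beforehand. However, the lower whole numbers behind the X scores, given next, could by themselves give a ratio in this range. The test therefore cannot tell whether noise is the cause for the paired regions. Noise in regions called in only 1 replicate was not measured and stays open too. With the scores read as ratios of whole numbers, the median denominator on the X was 0.78 times the autosomal one in replicate 1 and 0.77 in replicate 2, and the median numerator 0.87 and 0.86 times (in the combined list 0.72 and 0.77), with ranges over 3 choices of the constant in the 3 lists of 0.71 to 0.87 and 0.77 to 0.92. Fewer X copies in embryos of both sexes may contribute, but the labels state no sex and the numbers cannot be tied to reads, so a normalization that treats the X differently and a true difference in Chromator occupancy both stay open, and no biological explanation was tested.

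More regions per gene on chromosome 4 were weighed next. Per Mb of sequence it had 30.3 regions found in both replicates (21.8 to 41.1), against 28.6 on the large arms. Chromosome 4 held 80 genes on 1.35 Mb, and the large arms 13842 on 119 Mb. The ratio per gene of regions found in both replicates thus mostly reflects fewer genes per length and is no sign of denser Chromator regions. The combined list differed, with 58.4 regions per Mb on chromosome 4 (exact Poisson interval 46.3 to 72.8) against 45.6 on the large arms. That interval treats clustered regions as independent and is too narrow. Broad domains split into several regions as the whole cause are argued against, since merging regions within 5 kb raised the ratio to the large arms to 2.57 (exact interval 1.76 to 3.61). Longer genes may account for the ratio, since per Mb of summed gene length it was 1.09 (0.78 to 1.49), and an excess of up to the upper bound is not excluded. Summed gene length was 1.05 Mb on chromosome 4 and 95.1 Mb on the large arms, close to the length of sequence in both. This value thus nearly restates the comparison per Mb of sequence and is no separate support. Gene numbers and lengths come from Release 6 while the regions are on release 5, and whether the regions lie in genes was not tested, nor was any biological explanation.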
